A study of Caenorhabditis elegans with 2 samples.

How the data were processed

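ChIP-seq with an anti-GFP antibody was done on whole hermaphrodite L1 larvae of strain OP481, 6 h after synchronization, in 2 biological replicates of 1 group, per the labels. The labels name the antibody target as nhr-47 in one field and describe an anti-GFP immunoprecipitation in another. The strain carries the transgene wgIs481, which expresses NHR-47 with a C-terminal GFP-FLAG tag, in an unc-119 mutant background.

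The deposited files are region lists in the narrowPeak layout. For each replicate, and for both replicates pooled, the authors deposited a relaxed list of 30000 regions called against a control as input for the irreproducible discovery rate (IDR), and a list thresholded by the optimal IDR rule, each on ce10 and ce11, per the submitters' file index. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. Column 7 of each deposited list holds the caller's signal value, which the authors left in units of the caller's enrichment score and which rises with depth. Column 9 holds the -log10 of the q value, as the authors deposited it. Column 10 of the deposited lists, of another kind, is the offset of the summit from the region's start. The score column was 0 and the p column -1 throughout, so neither was used. Read counts and library totals were not analysed here, so the depth per sample is unknown and no interval that needs it is given. Intervals on shares of peaks or genes cover counting error only. For a count of 0, the share allowed is 3 counts of the total, and the two-sided exact interval drawn in the plot of gene lists reaches higher, to 4.3% for the intestine markers.

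The pooled ce11 lists were the basis of peak positions, counts and sequence tests, and the replicate lists that of the replicate values and single-replicate alternatives, with the reference genome WBcel235 and the Ensembl release 115 annotation. The ce10 thresholded list was used only for its number of peaks, and coordinates were not converted between builds. Every region lay within the chromosome lengths of the reference. The mitochondrial genome was left out. Of the thresholded list, 5291 of 5357 intervals were distinct, since some intervals are listed more than once with different summits. Each summit counted once, and 1 summit that lay outside its interval was kept. There were 0 unused per-sample columns.

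A replicate value of a thresholded peak was the signal of the region in that replicate's list that overlapped it by at least 1 bp and had the nearest summit. It was divided by the median over peaks found in both replicates, and the mean and SD of the 2 replicates are given. Promoters ran from 500 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Summits outside promoters were assigned to exons, then introns of protein-coding genes, then intergenic sequence. Shares were compared with 1000 sets of uniform positions on the same chromosomes, and replicate overlap with 1000 circular shifts. Shares of X and of the central 50% of chromosomes were tested with two-sided exact binomial tests. Gene lists and classes of noncoding genes were tested with two-sided Fisher's exact tests, with other protein-coding genes as the background, adjusted by Benjamini-Hochberg at 0.05. Lists were made from gene symbols, by the start of the symbol, by named genes or by both. Of the listed symbols, 1 intestine marker and 1 body wall muscle marker were not found in the annotation. Genes next to each other can share a summit, as 532 summits lay in the window of 2 or more genes. Motifs and 6-base sequences were counted on either strand in 101 bp centred on the summit and in a window of the same size 300 bp to a randomly drawn side, and compared with exact McNemar tests. Log2 odds and log2 ratios include a pseudocount of 0.5. The comparison of 6-base sequences with others of like composition, and the tests of the closing section on sequence, were chosen after seeing the data.

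The rule for named genes, set with the gene lists, motifs and main alternatives before the data were examined, was as follows. For the 25 peaks of highest signal, the protein-coding gene with the nearest 5′ end was named. For each list past the threshold, up to 4 members with the strongest summit in their window were named, and for other lists up to 2. The genes nhr-47 and unc-119, all fixed motifs, at least as counts, and the 10 6-base sequences of lowest p were also named. The gene rpl-20, which shares the peak of rank 4, falls under the list rule.

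The list test was tested on simulated data with 19973 genes and 5357 random summits. Planted summits at 30% of the members of 4 lists were recovered in 80 of 80 cases, and 1 of 560 lists with nothing planted was called. With GACGCA planted in 5% of windows, the test of 6-base sequences recovered it in 5 of 5 simulations and called 23 of 10370 other sequences. The simulated lists were random genes of the real sizes, and the simulated summits were uniform positions. These rates therefore do not cover neighbouring list members that share summits, or a GC difference between summit and flank. Alternatives were the ce10 list, other overlap rules, the stronger 2678 peaks, peaks found in both replicates with 50% overlap, each replicate alone, promoter windows of 1000 or 300 bp upstream, all transcript 5′ ends, other expectations and backgrounds, circular shifts, and other motif windows and flanks. Assignment to the nearest 5′ end only, stratification by deciles of promoter GC content, and autosomal genes only were added after seeing the data. With 1 group there was no comparison between groups.

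Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.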

Results

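NHR-47, a member of the large nuclear hormone receptor family of the nematode Caenorhabditis elegans, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq), which recovers DNA fragments bound by a chosen protein. The worms carried a transgene for NHR-47 with a C-terminal GFP-FLAG tag, and an anti-GFP antibody was used. Whole hermaphrodite larvae of the L1 stage were collected 6 h after synchronization by bleaching and starvation. The study held 2 biological replicates of 1 group, with no second condition, so the comparisons were made between the replicates and between kinds of genomic region. Coordinates are on the ce11 build (WBcel235) and counted from 1. The files gave region lists with no read counts, so the depth of each library is unknown.

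The authors' thresholded list held 5357 peaks with a median width of 420 bp. The signal value, the authors' own score of each peak, ranged from 77.0 to 4060 with a median of 156. These peaks were the 5357 regions of highest signal among the 30000 regions of the authors' pooled list. The list made on the older ce10 build held 5358 peaks.

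The 2 replicates named largely the same places. When each replicate's list was limited to its 5357 regions of highest signal, 82.3% of the replicate 1 regions overlapped a replicate 2 region by at least 1 bp. Circularly shifted regions overlapped in 3.74% of cases on average and in 5.26% at most (two-sided permutation p = 0.002 by shifts, the smallest that 1000 of them can give). A region of both replicates overlapped 5312 of the thresholded peaks (99.2%), and 78.6% overlapped a region of that top set in both. The thresholded list was itself made from these 2 replicates, whose own lists held 30000 regions each. High overlap of its peaks thus follows in part from how they were chosen. Across these 5312 peaks the signal values of the replicates had a Spearman rho of 0.862, and the log2 signals a Pearson r of 0.902. The permutation p of rho was 1e-05, the smallest that 100000 permutations can give, and peaks are not independent replicates. After division by each replicate's median, the log2 ratio between replicates had an SD of 0.50, and 94.9% of peaks lay within 2-fold. No signal value was shared between the replicate lists, so the libraries were treated as separate.

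**Figure D1:**
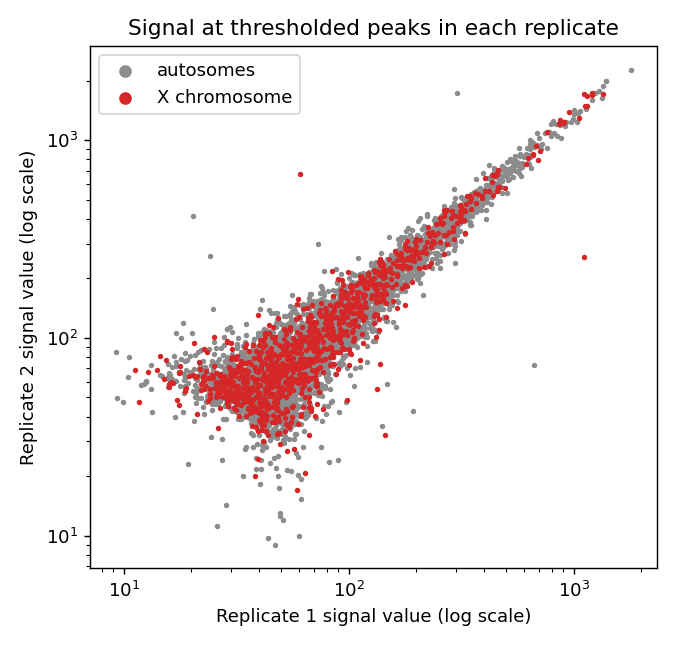
Signal value of the overlapping region in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for each thresholded peak with a region in both replicates, in arbitrary units of the authors' score; each point is 1 peak, red on the X chromosome and grey on autosomes. The points follow 1 diagonal, with a Spearman rho of 0.862 over 5312 peaks.

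The 25 strongest peaks included 4 at promoters of ribosomal protein genes and 8 on X outside promoters. The highest signal was upstream of rpl-3, a gene for a protein of the large ribosomal subunit, on III from 3867279 to 3867856, with a signal of 4060. Its summit lay 286 bp upstream of the gene's 5′ end. Relative to the median peak of each replicate, its signal was 25.8 ± 1.59 (SD, n = 2). The promoters of rpl-35 (18.9 ± 1.65, n = 2) and rpl-15 (16.4 ± 1.01, n = 2) were also among the 25 strongest. The peak of rank 4, nearest Y17G9B.5, lay in the promoter window of rpl-20 as well (20.3 ± 0.0014, n = 2). Other promoter peaks in this set were at tasp-1, a gene of the taspase family (21.2 ± 0.568), and at cdc-48.1, which encodes an AAA ATPase that unfolds ubiquitinated proteins (19.4 ± 0.0718). The promoter peak at cox-5A, a subunit of cytochrome c oxidase, reached 14.9 ± 0.257, and that at ints-4, a subunit of the Integrator complex, 14.3 ± 0.715. The remaining promoter peaks of the set were at puf-9, tos-1 and Y22D7AL.10.

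Of the 25 strongest peaks, 11 had their summit in a promoter, 11 were intergenic, 3 were intronic and none was exonic. They included 9 peaks on X and 7 on III. Of the 16 autosomal peaks, 10 lay in promoters, against 1 of the 9 peaks on X. The X peaks outside promoters were nearest to the 5′ ends of W02H3.3, F20B6.9, K02D3.1, cest-16, ZK899.6, nspc-17, Y41G9A.17 and xol-1. The strongest of them was the intergenic peak on X from 11093735 to 11094575, 3985 bp downstream of the 5′ end of W02H3.3 and past its 3′ end (19.5 ± 1.13, n = 2). The peak nearest xol-1, the switch gene of sex determination, lay 4875 bp upstream of it, from 8035966 to 8036982 (14.6 ± 0.547, n = 2). Autosomal peaks of this set outside promoters were nearest to egg-5, ZK1248.17, cmd-1 (calmodulin), ins-13 (an insulin-like peptide), tag-340 and Y111B2A.12. Of these, the peaks nearest egg-5, ZK1248.17 and ins-13 lay in the window of an snRNA gene. All 25 peaks ranked among the first 100 regions in both replicates.

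Summits were concentrated just upstream of genes. A promoter window, from 500 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene, held 2094 of the 5357 summits (39.1%, 95% Wilson interval 37.8 to 40.4%). Uniform positions on the same chromosomes fell there in 12.8% ± 0.471 of cases (SD over 1000 sets), a ratio of 3.04. Exons held 4.11% of summits against 25.2% of random positions, and introns held 22.7% against 32.1%. Intergenic sequence held 34.1% against 29.8%. Each of these 4 differences reached the smallest two-sided Monte Carlo p of 0.002. The median promoter summit lay 162 bp upstream of the 5′ end. Among the 24643 pooled regions that did not enter the thresholded list, 15.3% of summits were in promoters. By rank, the promoter share was 57% in the first 100 peaks and 29.9% in the 2857 weakest thresholded peaks.

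Peaks were unevenly spread over chromosomes. Chromosome III held 64.1 peaks per Mb and X 62.1, against 39.9 on V. The X chromosome carried 1100 peaks (20.5%, 95% Wilson interval 19.5 to 21.6%) on 17.7% of the nuclear genome (two-sided exact binomial p = 6.89e-08). The difference was not past the threshold in the stronger 2678 peaks, where the ratio was 1.05 (exact p = 0.276). It was reversed against the pooled regions below the threshold, of which 22.5% were on X (ratio 0.915, exact p = 0.0007). Chromosome V carried 15.6% of peaks on 20.9% of the length (adjusted exact p = 3.35e-22), and III carried 16.5% on 13.7% (adjusted exact p = 4.08e-08). The shares on I and IV differed from their length by less, at ratios of 1.09 and 0.919, and the share on II did not differ (adjusted exact p = 0.581).

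The central 50% of the chromosomes held 60.2% of summits (95% Wilson interval 58.8 to 61.5%; two-sided exact binomial p = 2.56e-50). The share was 70.0% on V and 49.8% on X (exact p = 0.928 on X). Of protein-coding genes, 55.3% had their 5′ end there. Against the pooled regions below the threshold, the central share did not differ (ratio 1.01, exact p = 0.587). These tests treat peaks as independent, which clustered peaks are not.

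**Figure D2:**
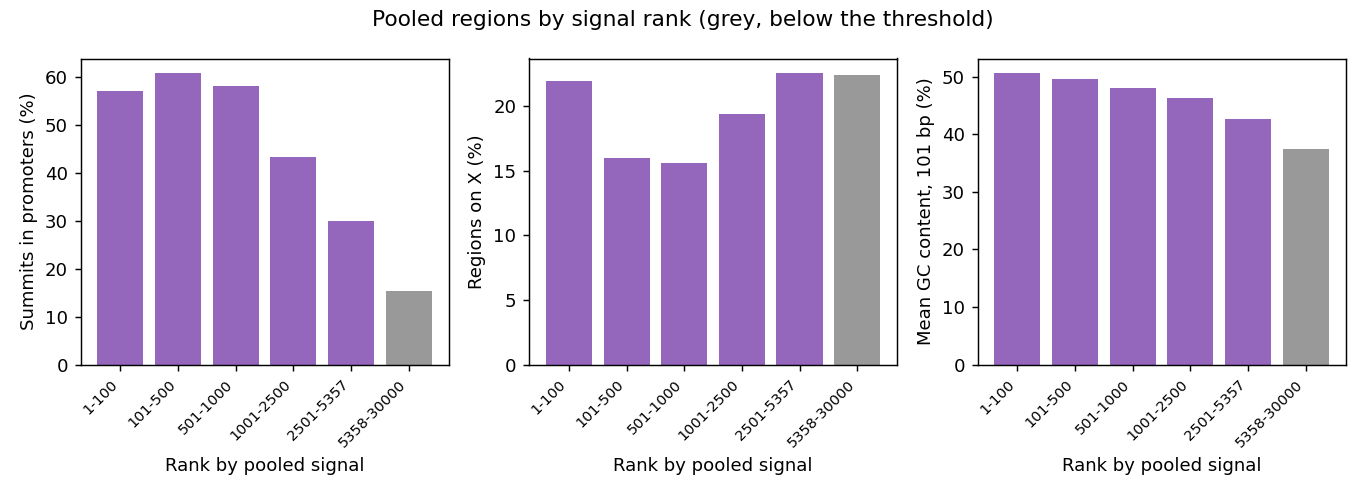
Share of summits in promoters (left), share of regions on X (middle) and mean GC content around the summit (right), each in percent, for pooled regions grouped by rank of signal (x axis); purple bars are thresholded peaks and the grey bar is the 24643 regions below the threshold. The promoter share is 57% in the first 100 peaks, 60.8% in the next 400 and 15.3% below the threshold, and mean GC content goes from 50.6% to 37.4%.

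Genes of several translation, energy and protein turnover lists carried promoter peaks more often than other genes. Of 19973 protein-coding genes, 2566 (12.8%) had a summit in the promoter window. Of the 32 gene lists fixed in advance, 10 had a higher share than all other genes and 10 a lower one (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 32 lists). The remaining 12 lists were not past the threshold. By circular shifts of the peaks, 12 lists were higher and 14 lower. Shifted peaks lose their preference for promoters, so fewer windows of any list hold one. A list well below other genes is then called lower whatever its size, so these counts add little to the exact tests.

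Ribosomal protein and translation factor lists stood highest. Of 78 ribosomal protein genes, 64 had a promoter peak (82.1%, exact 95% interval 71.7 to 89.8%; log2 odds 4.95, adjusted exact p = 1.19e-42). The log2 odds fell to 2.94 with a window from 300 bp upstream to 100 bp downstream. They were 3.23 with each summit given to the nearest 5′ end only, and both calls held. Among 39 translation factor genes 26 had a promoter peak (66.7%, adjusted exact p = 9.57e-14). The strongest was at iff-2, an eIF5A gene, with a relative signal of 11.8 ± 0.203 (SD, n = 2). The translation factor genes eif-3.C (8.42 ± 0.167), eif-3.B (8.39 ± 0.142) and eef-1A.1 (7.03 ± 0.332) followed. Of 70 mitochondrial ribosomal protein genes, 28 had a promoter peak (40%, adjusted exact p = 5.17e-08), with mrpl-28 at 7.88 ± 0.353, mrps-7 at 6.54 ± 0.132, mrpl-55 at 4.88 ± 0.178 and mrps-35 at 3.86 ± 0.528. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had a peak at 11 of 32 genes (34.4%, adjusted exact p = 0.00367). Their strongest were ears-2 (4.46 ± 0.0216), kars-1 (2.52 ± 0.0589), nars-1 (2.37 ± 0.079) and mars-1 (2.33 ± 0.212).

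Energy and protein turnover genes were also higher. Proteasome subunits had a peak at 20 of 33 genes (60.6%, adjusted exact p = 9.6e-10), led by rpn-3 (7.44 ± 0.196), rpn-11 (4.49 ± 0.276), rpt-2 (3.51 ± 0.0594) and pbs-1 (3.01 ± 0.362). The summit at rpn-3 also lay in the window of hsp-110. Oxidative phosphorylation genes had one at 20 of 38 (52.6%, adjusted exact p = 2.46e-08), with cox-5A strongest, then atp-1 (8.28 ± 0.647), cox-5B (5.86 ± 0.349) and cyc-1 (3.83 ± 0.15). The V-ATPase, the proton pump that acidifies lysosomes, had 7 of 20 genes with a peak (35%, adjusted exact p = 0.0163). Its strongest were vha-8 (4.68 ± 0.697), vha-12 (4.66 ± 0.0946), vha-15 (2.18 ± 0.152) and vha-1 (1.94 ± 0.0955). Autophagy and lysosome genes had 11 of 31 (35.5%, adjusted exact p = 0.00295), among them lgg-2 (7.05 ± 0.35), epg-7 (6.56 ± 0.14), epg-8 (3.32 ± 0.813) and atg-18 (1.99 ± 0.212).

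Genes of the cell cycle and DNA replication had a promoter peak at 17 of 36 (47.2%, adjusted exact p = 2.04e-06). They included pcn-1, the sliding clamp of DNA polymerase (10.2 ± 0.909, SD, n = 2), efl-1, an E2F factor (6.82 ± 0.22), lin-35, the retinoblastoma homolog (5.48 ± 0.521), and cdc-6, a replication licensing factor (5.14 ± 0.542). Histone genes had one at 18 of 72 (25%, adjusted exact p = 0.00853), with his-37 at 12.05 ± 0.294, his-35 at 2.9 ± 0.0881, and his-67 and his-68 sharing 1 peak at 5.16 ± 0.529. The histone call was lost in 4 of 13 alternative settings, among them replicate 2 alone (adjusted exact p = 0.0512).

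Of the 10 lower lists, chemoreceptors had the lowest p, while the lists with no peak, given below, had the lowest shares. Chemoreceptor genes had a promoter peak at 20 of 1309 (1.53%, adjusted exact p = 5.36e-52), the strongest at srh-16, sri-5, srh-269 and srh-2. C-type lectins had 3 of 240 (1.25%, adjusted exact p = 5.87e-10), namely clec-126, clec-57 and clec-87. Neuropeptide and insulin-like peptide genes had 2 of 140 (1.43%, adjusted exact p = 4.96e-06), nlp-4 and nlp-3. Regions below the threshold alone lay at 28.6% of these peptide genes, against 15.5% of all protein-coding genes. That share was 3.75% for C-type lectins and 6.8% for chemoreceptors. The peptide list was thus low in peaks past the threshold, not in regions of any strength. The F-box A, B and C families had 15 of 322 (4.66%, adjusted exact p = 4.5e-06), led by fbxb-85, fbxb-72, fbxb-88 and fbxa-84. Only 2.17% of F-box genes held a region below the threshold alone, against 15.5% of all protein-coding genes. Among genes with any pooled region, the F-box direction turned, without passing the threshold. Of 3 detoxification lists, 2 were lower, with 2 of 74 cytochrome P450 genes (cyp-13A2 and cyp-33C4, adjusted exact p = 0.00893) and 1 of 67 UDP-glucuronosyltransferases (ugt-20, adjusted exact p = 0.00375). Both calls were lost within deciles of promoter GC content by the Mantel-Haenszel test, with log2 odds close to those without deciles (-1.97 against -2.10 and -2.71 against -2.71). Glutathione S-transferases, with 6 of 44, did not differ from other genes at the threshold (adjusted exact p = 0.876). Collagens had 9 of 156 (5.77%, adjusted exact p = 0.00971), including col-38, col-71, col-166 and col-148. Some of these sizes differed in 1 replicate alone. Neuropeptide log2 odds were -3.04 with both, -1.62 in replicate 2 and -2.20 in replicate 1. In replicate 1 alone, log2 odds were -2.71 against -3.34 for C-type lectins, -1.99 against -2.71 for UDP-glucuronosyltransferases and -1.24 against -2.10 for cytochrome P450 genes, whose call was lost.

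No promoter peak was found at any of the 84 intestine markers, which allows a share of up to 3.57% (adjusted exact p = 5.98e-05). This list held all genes whose symbol starts with lys, spp, asp or cpr, beside named genes such as elt-2. Their expression in the intestine was not checked, so the result is about the list rather than the tissue. The 47 major sperm protein genes had 0, which allows up to 6.38% (adjusted exact p = 0.00703). Regions below the threshold lay at 0% of them too, against 15.5% of all protein-coding genes. How well reads can be placed at this family, or at the F-box families, was not examined. The limit covers counting error only, so the lack of peaks does not show that the protein is absent there. The 33 germline markers had 0, which allows up to 9.09% (adjusted exact p = 0.0278). In replicate 2 alone, the germline log2 odds were -1.69 against -3.31, and the call was lost (adjusted exact p = 0.155).

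Nuclear hormone receptor genes, the family of NHR-47 itself, had a promoter peak at 34 of 274 (12.4%), close to the 12.9% of other genes (adjusted exact p = 0.957). Among only genes with a region of the pooled list in the window, the receptor list was lower (log2 odds -0.80, adjusted exact p = 0.0239). The strongest were at nhr-1 (2.95 ± 0.633, SD, n = 2) and nhr-158 (2.75 ± 0.169). Body wall muscle markers had 9 of 34 (26.5%, adjusted exact p = 0.0515), including act-4 and act-2, and heat shock proteins had 6 of 22 (27.3%, adjusted exact p = 0.0786), including hsp-1 (12.5 ± 0.821) and hsp-110. Neuron markers had 8 of 43 (18.6%, adjusted exact p = 0.324), with ric-19 and egl-21 strongest. The shares were 15% of the insulin and dauer pathway (daf-16 and daf-15 strongest) and 13.6% of glutathione S-transferases (gst-27 and gst-43). They were 9.68% of fatty acid oxidation genes (cpt-2 and ech-5) and 9.52% of pharynx markers (phat-6 and tbx-2). Homeodomain, bHLH and T-box factors stood at 8.2% (ceh-38 and hlh-11), lipases and lipid binding proteins at 7.32% (lbp-9 and lbp-4) and hypodermis and cuticle markers at 7.14% (bli-6 and wrt-3). Fatty acid synthesis and desaturation had 0 of 20, which allows up to 15% (adjusted exact p = 0.138).

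When the background was limited to genes with any region of the pooled list in the window, 6 of the 10 higher lists and 4 of the 9 lower lists that could be tested kept their call, since no major sperm protein gene held such a region. The V-ATPase odds then turned to -0.0747 and the F-box odds to 1.32 on the log2 scale, with adjusted exact p of 1 and 0.109. Of 13 alternative settings, this background included, the germline call was lost in 9, the V-ATPase and cytochrome P450 calls in 5 each and the histone call in 4. The call of aminoacyl-tRNA synthetases was lost in 3 and that of autophagy genes in 2. Those of cell cycle, UDP-glucuronosyltransferase, collagen, C-type lectin, F-box and, of 12 settings, major sperm protein lists were lost in 1 each. In replicate 1 alone, the calls of aminoacyl-tRNA synthetases (adjusted exact p = 0.0502) and cytochrome P450 genes (0.083) were lost. In replicate 2 alone, those of histones (adjusted exact p = 0.0512) and germline markers (0.155) were lost, and body wall muscle markers were called higher (0.0165). The body wall muscle list was called higher in 5 of its 13 alternatives and the heat shock list in 6. By circular shifts, the homeodomain, fatty acid synthesis, lipase and hypodermis lists were called lower (adjusted permutation p = 0.00256 each). Since shifted peaks lose their preference for promoters, shares this far below other genes could give no other call. These calls therefore do not show that the lists differ from other promoters. The insulin and dauer list was called higher with a window of 1000 bp upstream (adjusted exact p = 0.0446), and fatty acid synthesis lower against the background of pooled regions (adjusted exact p = 0.049).

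**Figure D3:**
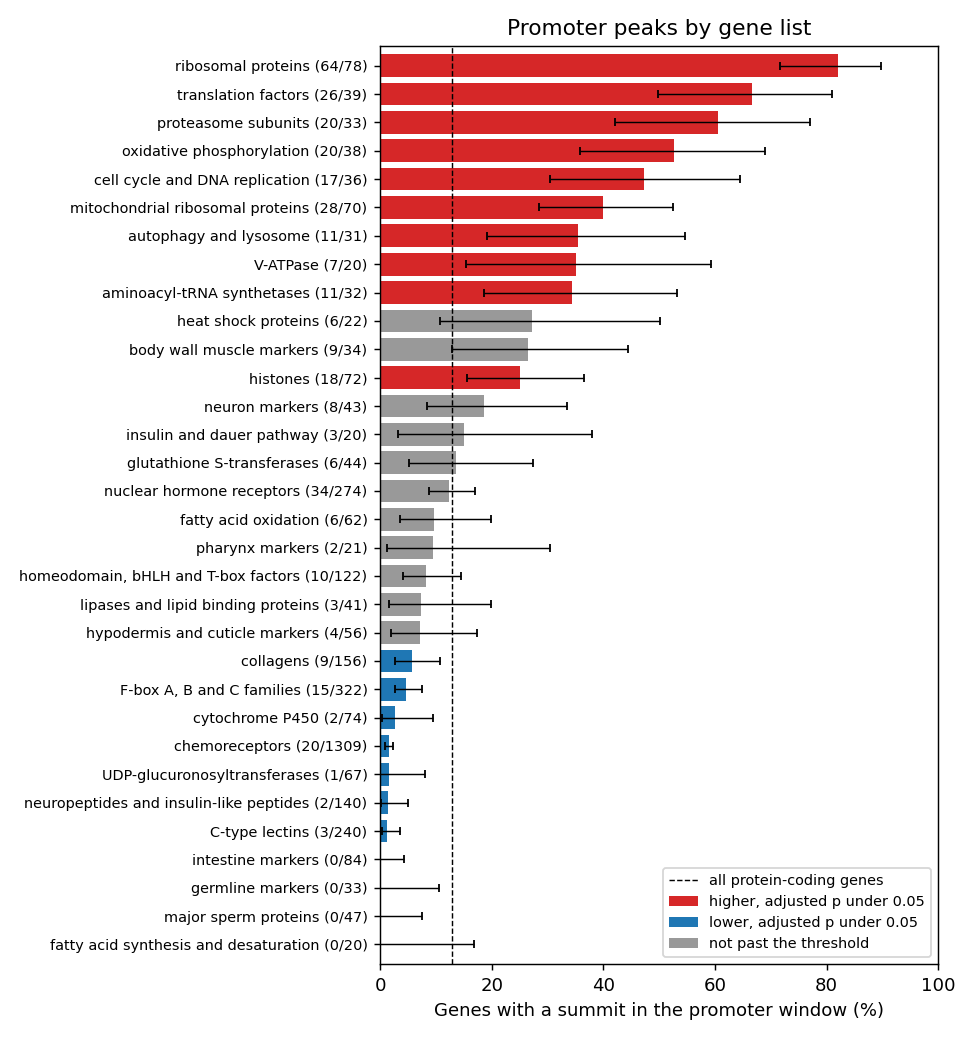
Percent of the genes of each list with a summit in the promoter window (x axis); bars are shares with exact 95% intervals, and the counts stand beside the list names. Red lists were higher and blue lists lower than other genes, grey lists were not past the threshold, and the dashed line marks the 12.8% of all protein-coding genes. The ribosomal protein list stands highest at 82.1%.

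Genes transcribed into structural RNAs carried peaks more often than protein-coding genes. Of 612 tRNA genes, 264 had a summit in the window from 500 bp upstream to 200 bp downstream of the 5′ end (43.1%, exact 95% interval 39.2 to 47.2%; log2 odds 2.36, adjusted exact p = 1.16e-72). The share was 32.1% of 346 snoRNA genes (adjusted exact p = 1.17e-19) and 27.1% of 129 snRNA genes (adjusted exact p = 2.05e-05). Of 261 miRNA precursors, 14.9% had one (adjusted exact p = 0.307). Summits in tRNA windows made up 4.63% of all summits, with none among the first 100 peaks and 6.87% in the 1500 peaks that follow rank 1000.

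Sequence at the summits was rich in GC and in GA repeats. GC content averaged 44.8% ± 8.37 (SD over 5357 peaks) around the summit and 35.0% ± 8.33 in windows 300 bp to one side. Of the 21 motifs fixed in advance, 8 were found more often at the summit than in the flank and 5 less often (exact McNemar test, adjusted over 21 motifs). The sequence GCGC was present at 36.9% of summits and 10.3% of flanks (log2 ratio 1.85, adjusted exact p = 8.21e-232), and the GA repeat GAGAGAGA at 5.88% and 0.933% (log2 ratio 2.64, adjusted exact p = 7.25e-50). Also higher were the Sp1-type GGGCGG (5.17% against 1.51%), the E-box CACGTG (5.39% against 1.85%), the bZIP element TGACGTCA (1.4% against 0.523%) and the E2F element (3.64% against 1.64%). The E-box CAGCTG (3.21% against 1.98%) and the DAF-16-type forkhead site (2.24% against 1.18%) were higher as well. The forkhead call was lost in the stronger 2678 peaks (log2 ratio 0.44, adjusted exact p = 0.262), and in each replicate alone (adjusted exact p = 0.108 in replicate 2 and 0.0835 in replicate 1), in peaks shared by both replicates with 50% overlap (0.31) and at summits outside exons and promoters (0.309). At the latter summits the TGACGTCA call was also lost (0.0799).

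The nuclear receptor half-site AGGTCA was found at 2.67% of summits and 2.43% of flanks (adjusted exact p = 0.542). The HNF4-type site AAGTCCA stood at 0.541% and 0.821% (adjusted exact p = 0.134), and the direct repeat AGGTCAAAG at 0.0933% and 0.0747% (adjusted exact p = 1). Taken in each replicate alone, the HNF4-type site was lower at summits, with log2 ratios of -1.24 in replicate 2 and -0.99 in replicate 1 (adjusted exact p = 0.000661 and 0.0102). Lower motifs were poly-T (4.46% against 12.4%), the GATA site TGATAA (5.94% against 9.8%), the homeodomain site TAATTA, the SKN-1-type site and the heat shock element. At summits outside exons and promoters, the call of TGATAA was lost (log2 ratio -0.27, adjusted exact p = 0.0533). The remaining motifs, extended GATA, AP-1, PHA-4-type forkhead, T-box and YY1-type sites, were not past the threshold. The extended GATA site was lower in the stronger 2678 peaks (log2 ratio -1.34, adjusted exact p = 0.000153), in peaks shared with 50% overlap (-0.85, 0.00102) and in replicate 1 alone (-0.48, 0.0375). The PHA-4-type site was lower in replicate 2 alone (log2 ratio -0.10, adjusted exact p = 0.0474) and at summits outside exons and promoters (-0.31, 6.4e-06), and the T-box site was higher at the latter (2.81, 0.0205).

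Base composition tracked several of these differences. Sequences of 6 bases with as many G or C bases and CpG steps as TGATAA had a median log2 ratio of -0.71, against -0.72 for TGATAA itself. For TAATTA the values were -1.03 and -1.04, and for AGGTCA 0.14 and 0.14. CACGTG, at 1.54, stood above the median of 0.78 for its composition, at rank 23 of 220. CAGCTG, at 0.70 against 0.54, and the Sp1-type site, at 1.77 against 1.60, lay nearer to theirs, at ranks 89 of 258 and 8 of 19.

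Of all 2080 6-base sequences counted with their reverse complements, 815 were higher at summits and 572 lower. The 10 of lowest p were GAGAGA, AAAAAT, AAAATT, GACGCA, CGTCTC, ACGCAG, AGAGAG, TTAAAA, AGAGAC and CGCAGA. GAGAGA was present at 25.1% of summits and 6.14% of flanks (adjusted exact p = 1.72e-160), and GACGCA at 14.6% and 1.77% (log2 ratio 3.03, adjusted exact p = 1.81e-138). GACGCA ranked 1 of 220 among sequences of its composition, whose median log2 ratio was 0.78. AAAAAT, AAAATT and TTAAAA were lower at summits, with log2 ratios of -0.998, -1.14 and -1.48.

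**Figure D4:**
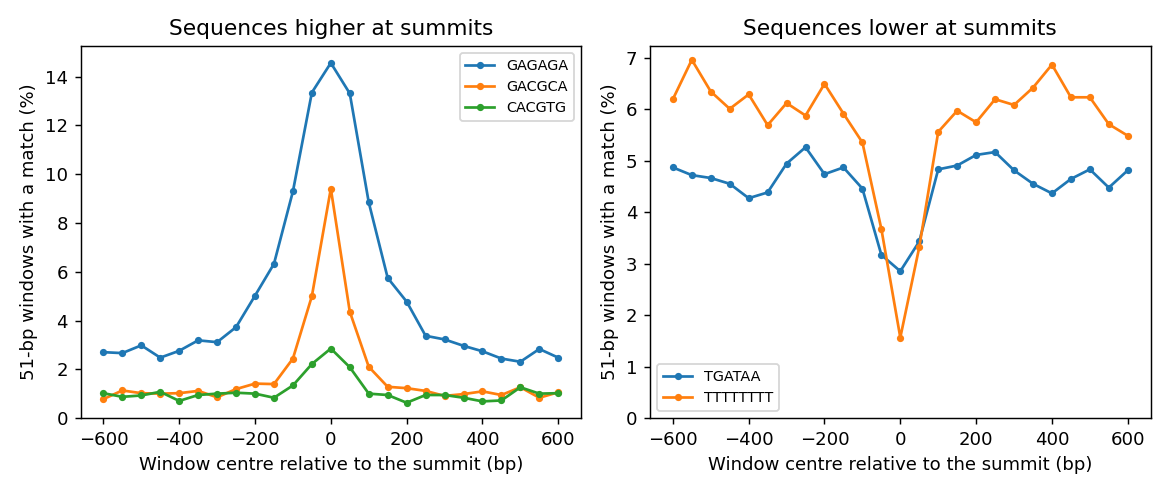
Percent of short windows with a match on either strand (y axis) against the position of the window relative to the summit in bp (x axis), over 5357 peaks; lines join neighbouring windows, sequences higher at summits on the left and lower on the right. GACGCA is found in 9.41% of windows at the summit and 0.859% at 300 bp on the side of lower coordinates, and poly-T falls to 1.57% at the summit.

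No peak lay near nhr-47, and 4 lay near unc-119. No thresholded peak, and no region of the pooled list or of either replicate, had its summit within 20 kb of nhr-47 (V, 5505253 to 5509956). Of all protein-coding genes, 23.1% had no thresholded peak within 20 kb, and the median gene had 2. The share of genes with no region of the pooled or replicate lists was not computed. Around unc-119 the pooled, replicate 1 and replicate 2 lists held 9, 11 and 8 regions. The transgene brings extra copies of nhr-47, and how these change the reads there was not tested. The absence of a region thus does not show that the protein is absent there. The gene unc-119, carried as the rescue marker of a strain with a mutant unc-119 allele, lies on III from 10902641 to 10908935 and had 4 thresholded peaks within 20 kb. Fewer were found around 74.7% of genes. The strongest of the 4, with a signal of 339 and rank 1089, lay in an intron of unc-119, from 10903253 to 10903628 (relative signal 2.17 ± 0.276, SD, n = 2). In an intron, another reached rank 2449, and a weak exonic peak had rank 4905. The peak upstream of com-1, chosen after its values were seen as the remaining 1 of the 4, had rank 2948. Extra copies of unc-119 in the strain can add reads at the peaks inside that gene. Occupancy of unc-119 by the tagged protein cannot be told apart from this.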

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

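Nearest 5′ end assignment, GC deciles and autosomal genes only were settings chosen after seeing the data; the others were set before the data were examined. Of 91 alternative values of the main results, 85 kept their direction and their side of the threshold or stayed within 1.5 times a count. The exceptions were as follows. Keeping the stronger part of the list left 2678 peaks, by construction, and the excess of peaks on X was then not past the threshold, at a ratio of 1.05 to the share by length. Against pooled regions below the threshold, the X share was reversed, at a ratio of 0.915, and the central share of the chromosomes was no longer past the threshold, at 1.01; the cause was not tested. With a background of only genes that hold a pooled region, 6 lists were higher and 6 lower, in place of 10 and 10. Fewer genes were tested there, and the major sperm protein list, with no such gene, gave no value. In that setting the V-ATPase list turned to log2 odds of -0.0747 and the F-box list to 1.32, neither past the threshold. Each replicate alone gave 9 to 10 lists higher and 9 lower, and a promoter ratio of 3.05 to 3.09. No peak lay near nhr-47 in any of the 4 alternatives run. They could give nothing else, as no list held a region within 20 kb of it, and they count among the 85. Of 640 alternative values of single lists, classes, motifs and 6-base sequences, 572 were the same, 39 lost their call, 26 gained one, 2 reversed and 1 moved. The last was the count at unc-119, where 2 peaks remained in the stronger part of the list. Circular shifts of the peaks against gene lists count among these alternatives. They remove the preference for promoters, so they say little about single lists. No paired analysis was possible because there is 1 group. The depth is unknown, which limits what the absence of a peak can show.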

Other observations

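The tests of the 12-base sequence on X against autosomes, of recovery of transcribed genes, of GAGACGCAG by place, of any pooled region at intestine markers, and of GC content and shared summits for the V-ATPase and histone lists were chosen after the result was seen. Of the 10 sequences of lowest p, GACGCA, CGTCTC, ACGCAG, AGAGAC and CGCAGA overlap in a longer run. Its part GAGACGCAG was found at 450 of 5357 summits and 20 flanks (8.4% against 0.373%), with no test, since it was assembled from the same windows. It was present at 8.74% of promoter peaks, 9.36% of intergenic, 7.15% of intronic and 4.09% of the 220 exonic peaks. Peaks in tRNA windows had it in 1.61% of cases, against 8.73% of other peaks (Fisher's exact p = 5.74e-06). It was rarer on X (5.09%) than on autosomes (9.26%, Fisher's exact p = 4.3e-06).

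The strong peaks outside promoters on X shared a sequence. From general knowledge of sites where the dosage compensation complex is recruited to X, the 12-base sequence TCGCGCAGGGAG was searched within 100 bp of each summit. Of the 8 X peaks outside promoters among the 25 strongest, 6 matched at least 11 of its 12 bases, while no autosomal peak of that set matched 10 or more. Among the first 1000 peaks, 12 of 164 on X and 0 of 836 on autosomes matched 11 or more bases. The 12 were nearest W02H3.3, F20B6.9, cest-16, nspc-17, Y41G9A.17, xol-1, F22H10.2, gtr-1, T27A8.7, C41A3.2, col-185 and R04E5.9, the last 6 named after their values were seen. Over all ranks, 18 of 1100 X peaks and 1 of 4257 autosomal peaks matched 11 or more bases, and 6 of the 18 ranked below the first 1000. The 18 had a median rank of 40, against 3000.5 for other X peaks, and 16 lay outside promoters.

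Composition in single bases was argued against. Of 200 shuffled versions, 0% matched as many X peaks of the first 1000 as the 20 with 10 or more bases matched. Over all ranks, 0% matched as many as the 39. Shuffling breaks up short runs such as GCGC, which was present at 36.9% of summits and 10.3% of flanks. Composition in runs of neighbouring bases thus stays open. The share with 10 or more bases was higher on X (12.2%) than on autosomes (1.2%, Fisher's exact p = 4.75e-10) in the first 1000 peaks, and 2.03% against 0.994% below them (Fisher's exact p = 0.0171). Matches away from peaks were not counted. An excess of the sequence on X as a whole thus cannot be told apart from an excess under these peaks. A scaling of the whole X chromosome could raise other peaks on X as well. Promoter peaks on X had a median signal below that on autosomes (ratio 0.75, bootstrap 95% interval 0.638 to 0.851). Peaks outside promoters with no match had a ratio of 0.981 (0.937 to 1.04). The 18 matching peaks lay 12.3-fold above the autosomal median, with an interval of 1.41 to 15.5. That interval reaches below a 2-fold limit set before this comparison, which was itself chosen after seeing the data. Only peaks past the threshold enter these medians, and a scaling could also carry weak X regions over it. The medians thus cannot decide on a scaling of X. A candidate explanation is that the tagged protein, or chromatin recovered with it, is concentrated at recruitment sites of dosage compensation. Whether NHR-47 itself is needed stays open, since no untagged control was analysed here.

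The peaks of the 10 higher lists could come from GC-rich promoters, but within deciles of promoter GC content the odds ratio of the ribosomal protein list was 24.5, with a lower 95% limit of 13.7, and 8 of the 10 lists kept their call. The V-ATPase odds ratio moved little, from 3.66 to 3.06 (95% interval 1.2 to 7.81), its call ending after adjustment over 32 lists, and that of histones was 1.48 in place of 2.27 (0.858 to 2.55), so GC content stays open for both. As the whole cause, summits shared with a neighbouring gene were argued against for 9 of the 10 lists. These stayed higher when each summit was given to the nearest 5′ end only. Histones did not (log2 odds 0.72 against 1.21, adjusted exact p = 0.246), so shared summits stay open there. For ribosomal proteins the log2 odds fell from 4.95 to 3.23, so shared summits could account for part of that difference. Broad recovery of highly transcribed genes, whatever the tagged protein, stays open for all 10, since the 43.1% of tRNA genes with a peak is what it could give, and no other immunoprecipitation or biological explanation was tested.

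None of the 84 genes on the list of intestine markers had a promoter peak, against 12.9% of other genes. Regions below the threshold did not make up this difference. Any region of the pooled list lay at 9 of the 84 (10.7%), against 28.4% of other genes (Fisher's exact p = 0.000138). This count includes the thresholded peaks, so it holds the same difference again and cannot decide on the threshold as the cause. The pooled list is itself limited to a set number of regions, so weaker occupancy can be missing from it. Regions only below the threshold lay at 10.7% against 15.5% of other genes (Fisher's exact p = 0.289). Genes with a thresholded peak cannot enter that count. Whether the threshold hides part or all of the occupancy thus stays open. The small number of intestinal cells in a whole larva was not tested.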
